A study of Escherichia coli str. K-12 substr. MG1655 with 8 samples.

How the data were processed

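RNA from 8 cultures of E. coli K-12 MG1655 was sequenced, 2 libraries for each of the groups labelled WT/Fe, WT/DPD, Δfur/Fe and Δfur/DPD. The deposited table gave FPKM per gene and library, made by the authors; the unit sets fragments against transcript length and library size. Per the submitters' processing notes, Bowtie 1.0.0 and Cufflinks 1.3.0 were used with the genome build ASM584v2; the notes do not say which tool made which step or in which order. Whether counting used strand was not given in the sources used here, so reads of overlapping or antisense genes may be shared, as may those of near-identical copies such as gadA and gadB or argF and argI. The table held 4595 lines, of which 1 carried no identifier and was left out of all tests, and 4462 of the other 4594 identifiers matched a symbol in a reference annotation of the same build. Summed FPKM ran from 5.60e+06 to 9.40e+06 per library, and tRNA genes held 56.2 to 62.8% of the sums.

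The depth was read from the FPKM values themselves. In each library a grid search over total fragments and mean fragment length sought the pair that turned 80 low values of genes of at least 500 bp into whole fragment numbers, and 95 to 100% of them fell within 0.05 of a whole number. On 4 simulated libraries this recovered the fragment length without error and the total within 0.0531%. These libraries were made with the FPKM formula that the search inverts, and their fragment lengths lay on its grid. The recovery therefore tests the search alone, and a different FPKM model was not simulated. The fitted totals were 1.01e+07 and 8.34e+06 fragments in WT/Fe, 9.95e+06 and 9.52e+06 in WT/DPD, 1.11e+07 and 1.01e+07 in Δfur/Fe, and 1.10e+07 and 1.13e+07 in Δfur/DPD.

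Log2(FPKM + 1) values of the 3484 genes with a mean of at least 5 FPKM over the 8 libraries were fitted with limma 3.58.1 in R 4.3.3, in a model with 1 mean per labelled group, 4 residual degrees of freedom and a spread shared by all groups. The contrasts were WT/DPD minus WT/Fe, Δfur/Fe minus WT/Fe, Δfur/DPD minus WT/DPD, Δfur/DPD minus Δfur/Fe, and the difference between the chelation responses (Δfur minus WT). Moderated tests with a trend of the prior variance on mean expression were two-sided, with Benjamini-Hochberg adjustment over all genes tested within a contrast, and a gene was called at an adjusted p under 0.05. Sets of genes from 36 lists, written from textbook knowledge, were compared with all other genes by camera with a preset correlation of 0.01 and again with an estimated one, with adjustment over the 35 lists of at least 4 tested members; 4 listed symbols were not in the table. With an estimated correlation, 4 of 22 called lists stayed called for WT/DPD minus WT/Fe, 4 of 26 for the difference of responses, and 0 of 20, 0 of 18 and 0 of 16 for the other contrasts. The list calls in those 3 contrasts were made only with the preset value. In Δfur/Fe minus WT/Fe the Suf, RyhB target and heat shock lists lost their call as well. Their estimated correlations of -0.0024, -0.026 and -0.015 lay below the preset 0.01. For these lists a larger correlation between genes therefore cannot account for the loss.

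The tests, contrasts, lists and alternatives were chosen before the data were examined. Some lists share members, so their results are not independent. The RyhB target list shares genes with the TCA cycle, iron storage and Isc lists, and arginine synthesis with pyrimidine synthesis. Genes were named by rule: for each contrast the 8 called genes of largest log2 fold change in each direction whose libraries did not overlap between groups (for the difference of responses, any called gene), up to 4 members of largest absolute change from each list spoken of, and fur in every library. Further members of a list, or genes of the same operon or pathway, were named after their values were seen. The correlation between comparisons sharing WT/Fe was set beside 100 simulations of unchanged groups. Alternatives were a pseudocount of 0.1 or 10, no filter or a mean of at least 20 FPKM, median-ratio scaling, quantile normalization, stable RNA and tRNA genes removed with rescaling, other variance models, the 4 libraries of a contrast alone, the replicate number as a block, each library left out, and a minimum absolute log2 fold change of 1. Protein-coding genes of at least 400 bp, and genes above 0 in all libraries, were added as alternatives after seeing the data.

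The tests were tested on simulated data made from the mean of each gene over the 8 libraries. Normal noise was drawn independently for each gene and library, with the same spread for a gene in all groups. The counts of false calls therefore hold only for groups of equal spread, and groups of unequal spread were not simulated. Among 3484 genes, 100 were changed by 1 and 100 by 2 on the log2 scale. For WT/DPD minus WT/Fe 87 and 94% of these were called with 9 false calls among 3284 unchanged genes, for Δfur/Fe minus WT/Fe 89 and 90% with 11, for Δfur/DPD minus WT/DPD 85 and 95% with 7, for Δfur/DPD minus Δfur/Fe 83 and 95% with 12, and for the difference of responses 67 and 91% with 5. Camera called 20 of 20 simulated lists of 15 genes moved by 0.5 and 1 of 20 unmoved ones. The genes of these lists were drawn independently, so false calls in lists of correlated genes were not tested. Tables and plots were made with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.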

Results

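Messenger and small RNA levels were measured by RNA sequencing in Escherichia coli K-12 MG1655, a laboratory reference strain, in cultures labelled as wild type or as lacking the gene for Fur, the ferric uptake regulator that represses iron acquisition genes when iron is plentiful. Per the labels, wild type (WT) and Δfur cells grew aerobically at 37 °C in M9 minimal medium with 0.2% glucose, either with 0.1 mM FeCl2 from the start (Fe) or with 0.2 mM of the iron chelator DPD for the last 2 h (DPD). The 4 groups are written here as WT/Fe, WT/DPD, Δfur/Fe and Δfur/DPD, by their labels, and held 2 libraries each, 8 in all, which the labels call biological duplicates. The series title names the Fur regulatory network as the subject, so each comparison asks which genes differ with iron supply or with fur. Steps in the low FPKM values placed the depth at 8.34e+06 to 1.13e+07 fragments per library, and a gene of 1000 bp at 5 FPKM then rested on 34.4 to 44.5 fragments. Values are FPKM as mean ± SD with n = 2, and fold changes are log2 differences ± SE of FPKM + 1, a scale that understates the change of low genes.

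The targeted gene went against the labels of 2 groups. The fur gene (b0683, protein-coding, 447 bp, positions 710200 to 710646 of the ASM584v2 chromosome) stood at 999 and 1081 FPKM in the libraries labelled WT/Fe and was listed at 0 in both libraries labelled WT/DPD. The libraries labelled Δfur/Fe held 805 and 841 FPKM, and those labelled Δfur/DPD held 0 and 1.499 FPKM. All groups below are named and compared by their labels, and no library was regrouped. The difference between the chelation responses has the same value whether or not the WT/DPD and Δfur/Fe labels are exchanged, while each of the other comparisons would become another one.

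The 4 libraries labelled WT and the 4 labelled Δfur also formed separate sets. The first principal component held 59.1% of the variance over the 3484 genes tested and 75.9% over the 2732 protein-coding genes of at least 400 bp, and it parted the sets in both. The fitted mean fragment length was 168 to 188 bp in the libraries labelled WT and 212 to 228 bp in those labelled Δfur. Exact zeros followed the same line: 11 genes of at most 363 bp lay above 50 FPKM in all libraries labelled WT and were listed at 0 in all 4 labelled Δfur, and 0 genes did so the other way. Apart from the longest they were at most 121 bp, shorter than the fitted mean fragment length of any library. Their zeros may depend on fragment length, so these genes are not a separate sign of the sets. Among them ssrA, the abundant tmRNA that rescues stalled ribosomes, was listed at 331749 and 318462 FPKM in WT/Fe, 435869 and 419522 in WT/DPD and 0 in all 4 libraries labelled Δfur, so a value of 0 in this table can be a failed estimate. The labels give no batch, and the sets cannot be told apart from the labelled genotype. Replicates within a group correlated at r = 0.994 to 0.998 across the genes of at least 400 bp and at 0.914 to 0.978 across all genes tested, where genes are not independent replicates. Across all genes tested the Δfur/DPD libraries correlated less with each other (0.914) than Δfur/DPD 1 did with Δfur/Fe 1 (0.926), and the third component set Δfur/DPD 2 apart (weight 0.85).

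**Figure D1:**
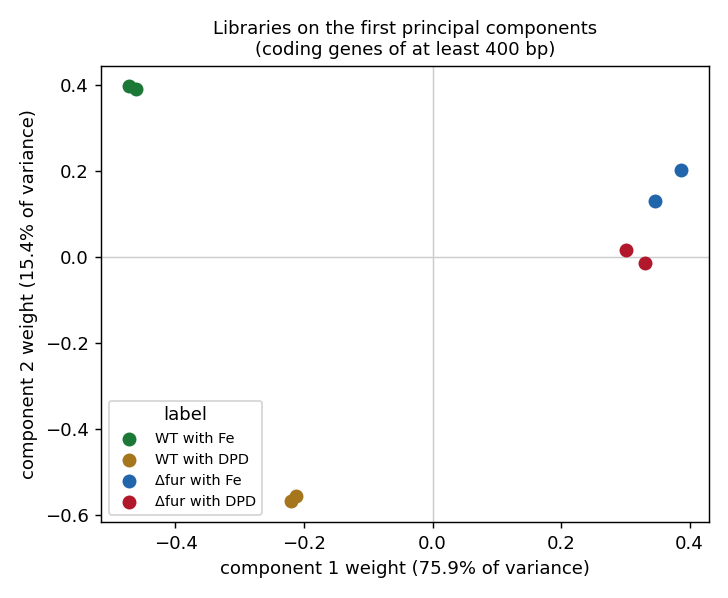
Weights of the 8 libraries on the first and second principal components of log2(FPKM + 1) over 2732 protein-coding genes of at least 400 bp, coloured by label, 2 points per group. The first component (75.9% of the variance) separates libraries labelled WT from those labelled Δfur, and the second (15.4%) separates WT/Fe from WT/DPD.

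Between the libraries labelled WT/DPD and WT/Fe, iron acquisition genes were higher. All 9 tested genes for enterobactin, the main siderophore of E. coli, rose (9 adjusted over the list alone), with a median log2 fold change of 5.49; camera gave adjusted p = 1.2e-11, and adjusted p = 0.097 with an estimated correlation. The isochorismate synthase gene entC stood at 30.4 ± 2.92 FPKM in WT/Fe and 2053 ± 55.0 in WT/DPD, a log2 difference of 6.03 ± 0.12, and entE, entB and ybdZ differed by 5.99, 5.71 and 6.26. All 26 siderophore uptake genes rose (26 adjusted over the list alone), led by the outer membrane receptor genes cirA (51.5 ± 6.57 against 5863 ± 51.5 FPKM, log2 6.81 ± 0.23), fepA (6.65) and fiu (5.52) and by the esterase gene fes (5.43). Camera gave adjusted p = 7.6e-21 for this list, and adjusted p = 0.097 with an estimated correlation. The small RNA ryhB, which represses mRNAs of iron-containing proteins, rose from 2421 ± 1723 to 151055 ± 10824 FPKM (log2 6.17 ± 0.51, limma adjusted p = 5.8e-04).

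Of 17 tested RyhB-repressed targets, 14 fell and 1 rose (15 and 1 adjusted over the list alone). Camera for the RyhB target list gave adjusted p = 1.8e-12, and adjusted p = 0.034 with an estimated correlation. The iron superoxide dismutase gene sodB fell by 5.11 on the log2 scale, from 1063 ± 26.2 to 29.8 ± 0.710 FPKM, and fumA, sdhB and sdhD differed at -2.39, -2.01 and -1.99. The 6 genes of the Suf iron-sulfur cluster pathway, used when iron is scarce, all rose (6 adjusted over the list alone), sufA by 3.42 and sufB by 2.79, from 50.3 ± 3.47 to 354 ± 1.29 FPKM. Camera for the Suf list gave adjusted p = 1.1e-07, and adjusted p = 0.041 with an estimated correlation. Of the 8 genes of the housekeeping Isc pathway 4 fell and 1 rose (5 and 1 adjusted over the list alone), iscR by 0.93 and iscX at -1.18. Camera for the Isc list gave adjusted p = 0.0036, and adjusted p = 0.28 with an estimated correlation. The manganese ribonucleotide reductase genes nrdH, nrdI and nrdE rose by 4.96, 4.95 and 4.53; in the list of paired manganese and iron enzymes 6 of 9 rose and 1 fell (7 and 1 adjusted over the list alone). Camera for the manganese and iron enzyme list gave adjusted p = 6.1e-04, and adjusted p = 0.26 with an estimated correlation. Iron storage genes bfr (-1.45), ftnA (-1.21) and ftnB (-1.14) fell, and dps did not pass the test (-0.38). That list had 3 of 4 lower (3 adjusted over the list alone). Camera for the iron storage list gave adjusted p = 0.0021, and adjusted p = 0.097 with an estimated correlation.

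TCA cycle and respiratory chain genes were lower in the libraries labelled WT/DPD. Of 17 TCA cycle genes 14 fell (14 adjusted over the list alone). Camera for the TCA cycle list gave adjusted p = 4.2e-13, and adjusted p = 0.058 with an estimated correlation. Of 21 genes of the aerobic respiratory chain 13 fell and 1 rose (13 and 1 adjusted over the list alone), among them nuoI (-1.74), nuoC (-1.73), nuoG (-1.71) and nuoH (-1.68) of NADH dehydrogenase I. Camera for the respiratory chain list gave adjusted p = 4.7e-08, and adjusted p = 0.11 with an estimated correlation. The zinc limitation genes fell in 6 of 7 cases (6 adjusted over the list alone): ykgM, for a zinc-free ribosomal protein, went from 18452 ± 812 to 43.9 ± 1.95 FPKM (log2 -8.68 ± 0.63), zinT from 13283 ± 484 to 90.7 ± 22.7 (-7.20 ± 0.77) and znuA, of the zinc importer, from 5486 ± 105 to 276 ± 47.6 (-4.32 ± 0.67). Camera for the zinc limitation list gave adjusted p = 3.7e-06, and adjusted p = 0.097 with an estimated correlation. The zinc exporter gene zntA rose from 4.33 ± 0.0755 to 85.0 ± 7.55 FPKM (4.01 ± 0.23), and the copper efflux genes cusC, cusB and cusF rose by 3.23, 2.86 and 2.84; 6 of 8 copper and zinc efflux genes rose and 2 fell, the same counts adjusted over the list alone, and camera gave adjusted p = 0.074. In the SOS response to DNA damage 15 of 16 rose (16 adjusted over the list alone), led by sulA (2.69), recN (2.35), umuD (1.72) and yebG (1.60). Camera for the SOS list gave adjusted p = 4.1e-11, and adjusted p = 0.034 with an estimated correlation. Of 15 heat shock genes 13 rose (14 adjusted over the list alone), led by ibpB (1.81) and ibpA (1.42). Camera for the heat shock list gave adjusted p = 4.3e-08, and adjusted p = 0.041 with an estimated correlation. Acid resistance genes went the other way, with 5 of 10 that fell (7 that fell and 1 that rose adjusted over the list alone). Camera for the acid resistance list gave adjusted p = 0.0018, and adjusted p = 0.23 with an estimated correlation.

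Among the genes of largest difference some were listed at 0 in WT/Fe: proK, a proline tRNA gene, at 0 and 0 against 693 and 323 FPKM, and the toxin gene tisB at 0 and 0 against 1118 and 146. The gene yjjZ was listed at 11.4 and 0 FPKM in WT/Fe and at 1374 and 1129 in WT/DPD, and the ribosomal protein gene copy ykgO fell by 7.39 on the log2 scale. In all, limma called 800 of 3484 genes between WT/DPD and WT/Fe at an adjusted p under 0.05, 499 higher and 301 lower. Median-ratio scaling gave 405 higher and 409 lower and quantile normalization 362 and 391, and leaving out WT/Fe 1, WT/Fe 2, WT/DPD 1 or WT/DPD 2 left 420, 444, 399 and 345 calls. The WT/DPD label is one of those that fur contradicted.

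**Figure D2:**
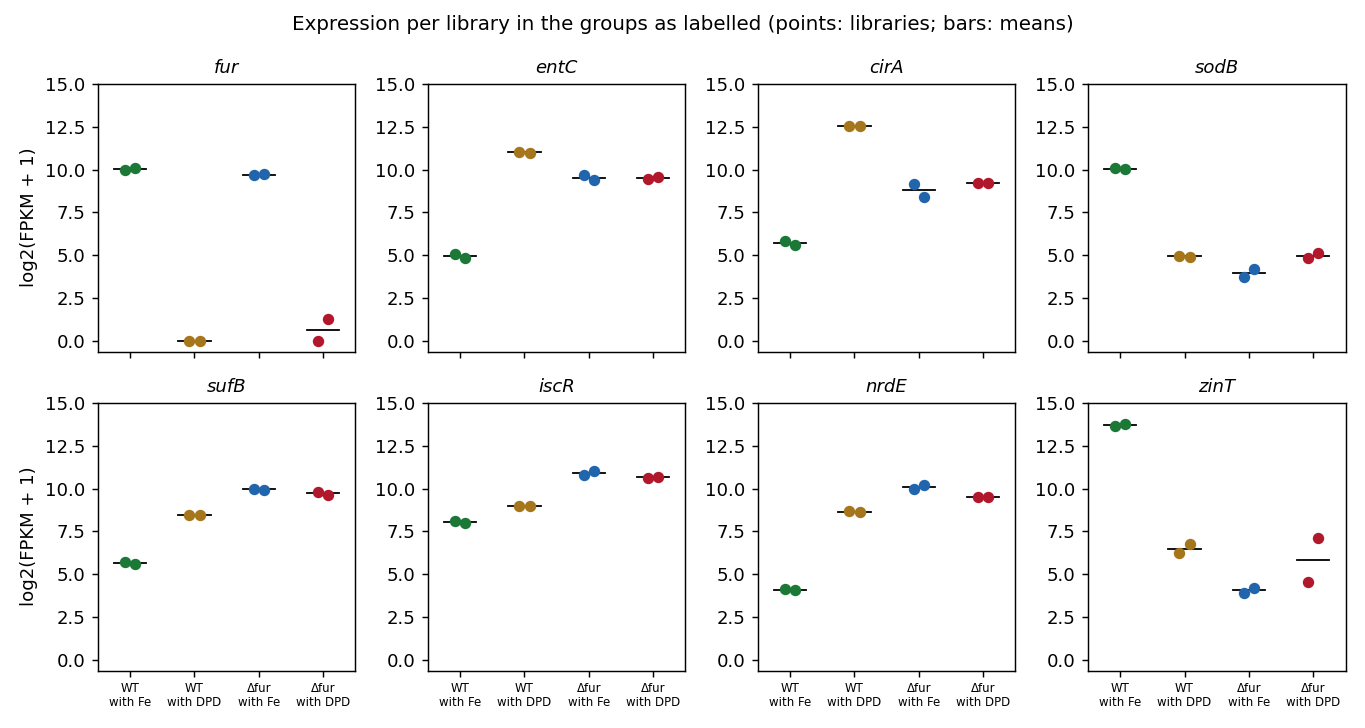
Log2(FPKM + 1) of 8 genes in each library, by labelled group, with points for the 2 libraries and a bar at their mean. The fur panel shows values near 1000 FPKM in WT/Fe, 805 and 841 in Δfur/Fe and at most 1.499 in both DPD groups, while entC, cirA, sufB and nrdE are low and sodB and zinT high in WT/Fe alone.

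Between the libraries labelled Δfur/Fe and WT/Fe the same iron genes were higher. All 9 enterobactin genes rose (9 adjusted over the list alone; median log2 fold change 4.89), with entF at 16.8 ± 3.40 against 735 ± 30.1 FPKM (5.38 ± 0.13), entH at 5.05 and ybdZ at 6.03. Camera for the enterobactin list gave adjusted p = 1.9e-04, and adjusted p = 0.28 with an estimated correlation. All 26 siderophore uptake genes rose (26 adjusted over the list alone), led by fes (5.29), fecR (4.32), fhuE (4.05) and fepA (3.75). Camera for the siderophore uptake list gave adjusted p = 3.7e-07, and adjusted p = 0.28 with an estimated correlation. The manganese ribonucleotide reductase operon rose as well, nrdI from 27.5 ± 1.98 to 3188 ± 449 FPKM (6.80 ± 0.13) and nrdH, nrdE and nrdF by 6.72, 5.99 and 5.59. The small RNA ryhB rose by 6.04 and mntH, for a manganese importer, by 3.64. The gene yjjZ was listed at 11.4 and 0 FPKM in WT/Fe and 3195 and 3089 in Δfur/Fe.

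All 6 Suf genes rose (6 adjusted over the list alone), sufA by 5.76 and sufB by 4.27, and 6 of 8 Isc genes rose while 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.14), with iscR at 280.0 and 251 FPKM in WT/Fe and 1783 and 2094 in Δfur/Fe (2.86 ± 0.10) and iscU by 1.74. Camera for the Suf list gave adjusted p = 8.2e-04, and adjusted p = 0.25 with an estimated correlation. Of 17 RyhB-repressed targets 12 fell and 4 rose (12 and 4 adjusted over the list alone), among them sodB (-6.08) and the succinate dehydrogenase genes sdhC (-4.62), sdhD (-4.61) and sdhB (-4.04). Camera for the RyhB target list gave adjusted p = 8.2e-04, and adjusted p = 0.25 with an estimated correlation. Of 17 TCA cycle genes 13 fell and 4 rose (13 and 4 adjusted over the list alone). Camera for the TCA cycle list gave adjusted p = 7.9e-05, and adjusted p = 0.28 with an estimated correlation. In the aerobic respiratory chain 18 of 21 fell and 1 rose (18 and 1 adjusted over the list alone), the riser being ndh (2.54). Camera for the respiratory chain list gave adjusted p = 7.8e-07, and adjusted p = 0.28 with an estimated correlation. The 9 ATP synthase genes all fell (9 adjusted over the list alone), led by atpE (-2.43). Camera for the ATP synthase list gave adjusted p = 1.9e-05, and adjusted p = 0.28 with an estimated correlation. The zinc limitation genes fell in 6 of 7 cases (6 adjusted over the list alone), ykgM at -11.31 and zinT at -9.61, and zntA rose by 3.56. Camera for the zinc limitation list gave adjusted p = 0.0012, and adjusted p = 0.28 with an estimated correlation.

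Growth and stress genes differed across the same pair. Of 54 ribosomal protein genes 46 fell (46 adjusted over the list alone; 34 under quantile normalization and 51 under median-ratio scaling), with a median of -0.82. Camera for the ribosomal protein list gave adjusted p = 9.5e-13, and adjusted p = 0.25 with an estimated correlation. All 15 general stress response genes rose (15 adjusted over the list alone), led by yjbJ (4.48), the trehalose synthesis gene otsB (3.42) and poxB (3.04). Camera for the general stress list gave adjusted p = 1.3e-05, and adjusted p = 0.28 with an estimated correlation. In pyrimidine synthesis 8 of 9 genes fell (8 adjusted over the list alone), with pyrB from 4504 ± 40.6 to 86.0 ± 63.7 FPKM (-5.92 ± 0.49), and all 11 arginine synthesis genes fell (11 adjusted over the list alone), led by carA (-4.50) and carB (-4.05). Camera for the pyrimidine and arginine lists gave adjusted p = 2.3e-04 and 1.2e-05, and adjusted p = 0.28 and 0.34 with an estimated correlation. Both lists hold carA and carB. Many of the genes with the lowest values were short and listed at 0 in Δfur/Fe, as were the leader peptide genes pheL (4126 and 4418 FPKM in WT/Fe) and leuL (1778 and 1721) and the tRNA gene proL (5409 and 813).

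In all, limma called 2492 of 3484 genes between Δfur/Fe and WT/Fe, 1520 higher and 972 lower, with a median log2 fold change over all genes of 0.21 against which the values above stand. Median-ratio scaling moved that median to -0.0079 and the calls to 1195 higher and 1230 lower. The fur gene itself did not pass the test here (limma adjusted p = 0.47), and the comparison crosses the 2 library sets, which no fit could separate from the labels.

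Between the libraries labelled Δfur/DPD and WT/DPD the siderophore genes were not higher. Of 9 enterobactin genes 5 fell (5 adjusted over the list alone), entD at -1.57 and entC at -1.49. Camera for the enterobactin list gave adjusted p = 0.012, and adjusted p = 0.48 with an estimated correlation. Of 26 siderophore uptake genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), with cirA at 5863 ± 51.5 in WT/DPD against 591 ± 3.98 FPKM in Δfur/DPD (-3.31 ± 0.23), fiu at -2.61 and fecR the riser at 0.75. Camera for the siderophore uptake list gave adjusted p = 0.0498, and adjusted p = 0.62 with an estimated correlation. All 6 Suf genes rose (6 adjusted over the list alone) and 7 of 8 Isc genes rose (8 adjusted over the list alone), sufA by 1.98, iscR by 1.66 and iscU by 1.62. Camera for the Suf and Isc lists gave adjusted p = 0.012 and 0.0035, and adjusted p = 0.41 and 0.41 with an estimated correlation. Among 17 RyhB-repressed targets 6 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of 0.04 and a mean of -0.12 of opposite sign (camera adjusted p = 0.54). The manganese importer gene mntH rose by 2.51 and dps, for the iron-binding protein of starved cells, from 1520.2 ± 14.1 to 11359.5 ± 636 FPKM (2.90 ± 0.18).

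Stress and amino acid synthesis genes differed as well. All 15 general stress response genes rose (15 adjusted over the list alone), among them yjbJ (3.66) and osmY (2.73), as did all 10 acid resistance genes (10 adjusted over the list alone), with gadA at 3.80 and gadB at 3.66, near-identical genes whose reads may be split. Camera for the general stress and acid resistance lists gave adjusted p = 4.5e-06 and 4.0e-05, and adjusted p = 0.41 and 0.41 with an estimated correlation. Of 11 methionine synthesis genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with the regulator gene metR from 125 ± 2.91 to 2289.9 ± 37.1 FPKM (4.19 ± 0.15) and metB and metA at 3.27 and 3.20. Camera for the methionine list gave adjusted p = 0.0011, and adjusted p = 0.48 with an estimated correlation. The 8 histidine synthesis genes all rose (8 adjusted over the list alone), hisH by 1.59. Camera for the histidine list gave adjusted p = 0.012, and adjusted p = 0.56 with an estimated correlation. Other synthesis genes were lower, with 10 of 11 arginine genes that fell (11 adjusted over the list alone), 8 of 9 pyrimidine genes (8 adjusted over the list alone) and 10 of 14 purine genes (10 adjusted over the list alone). Camera for the arginine, pyrimidine and purine lists gave adjusted p = 1.8e-04, 6.6e-04 and 1.5e-04, and adjusted p = 0.48, 0.41 and 0.47 with an estimated correlation. Of 16 aromatic amino acid synthesis genes 11 fell and 2 rose (11 and 4 adjusted over the list alone), and of 15 heat shock genes 9 fell and 2 rose (9 and 2 adjusted over the list alone). Camera for the aromatic and heat shock lists gave adjusted p = 0.0015 and 0.0037, and adjusted p = 0.47 and 0.41 with an estimated correlation. The 9 ATP synthase genes all fell (9 adjusted over the list alone), and 31 of 54 ribosomal protein genes fell (31 adjusted over the list alone; 20 under quantile normalization and 38 under median-ratio scaling). Camera for the ATP synthase and ribosomal protein lists gave adjusted p = 6.8e-06 and 1.8e-07, and adjusted p = 0.41 and 0.41 with an estimated correlation. Copper efflux genes fell, cusC at -5.93 and cusB at -3.81, within a list where 5 of 8 fell and 2 rose (5 and 2 adjusted over the list alone). Camera for the metal efflux list gave adjusted p = 0.020, and adjusted p = 0.41 with an estimated correlation. Outside the lists, yciG, yciF and ybgS rose by 4.07, 3.84 and 3.91, the pyruvate transporter gene btsT by 4.04 and dadA, of D-alanine breakdown, by 3.72. The alanine exporter gene alaE stood at 4.01 and 4.44 against 126 and 109 FPKM.

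In all, limma called 2040 genes between Δfur/DPD and WT/DPD, 1267 higher and 773 lower, against a median over all genes of 0.13; median-ratio scaling gave a median of -0.025 and 1005 higher and 1003 lower. The fur gene stood near 0 in all 4 of these libraries, and the comparison crosses the library sets.

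Between the libraries labelled Δfur/DPD and Δfur/Fe few iron acquisition genes were called. Of 26 siderophore uptake genes limma called 0 (0 adjusted over the list alone, and 5 at an unadjusted p under 0.05; camera adjusted p = 0.39), and of 9 enterobactin genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.23), entD by 0.79. Of 6 Suf genes limma called 0 (0 adjusted over the list alone, and 3 at an unadjusted p under 0.05), though the list as a whole lay lower, with a median of -0.23 (camera adjusted p = 0.015, and adjusted p = 0.34 with an estimated correlation). The gene ilvC, for ketol-acid reductoisomerase of branched-chain amino acid synthesis, fell by 4.73 on the log2 scale, from 8475 ± 2074 to 315 ± 35.9 FPKM (limma adjusted p = 4.2e-04). In that pathway 8 of 13 genes fell (9 adjusted over the list alone, beside 2 that rose so), with leuA at -1.33 and leuC at -1.18. Camera for the branched-chain list gave adjusted p = 3.8e-07, and adjusted p = 0.32 with an estimated correlation.

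All 8 histidine synthesis genes rose (8 adjusted over the list alone; median 1.42), with hisG from 253 ± 50.7 to 692 ± 79.7 FPKM. Camera for the histidine list gave adjusted p = 8.3e-08, and adjusted p = 0.35 with an estimated correlation. In methionine synthesis 9 of 11 rose (11 adjusted over the list alone), metC by 1.32 and metR by 1.20. Camera for the methionine list gave adjusted p = 3.8e-07, and adjusted p = 0.35 with an estimated correlation. In pyrimidine synthesis 6 of 9 rose (7 adjusted over the list alone, beside 1 that fell so), with pyrB from 86.0 ± 63.7 to 669 ± 67.7 FPKM (3.17 ± 0.49) and pyrI at 3.06. Camera for the pyrimidine list gave adjusted p = 0.0015, and adjusted p = 0.35 with an estimated correlation. Other synthesis lists had fewer calls: 2 of 11 arginine genes rose (11 adjusted over the list alone), 4 of 16 aromatic amino acid genes rose (9 adjusted over the list alone, beside 1 that fell so), 2 of 15 cysteine and sulfate assimilation genes fell (8 adjusted over the list alone) and 14 of 14 purine genes were not called. Camera for the arginine, aromatic and cysteine lists gave adjusted p = 1.1e-05, 0.0037 and 1.5e-04, and adjusted p = 0.41, 0.45 and 0.45 with an estimated correlation. Of 10 acid resistance genes 6 rose (8 adjusted over the list alone). Camera for the acid resistance list gave adjusted p = 5.6e-06, and adjusted p = 0.32 with an estimated correlation. Higher genes outside the lists were btsT (3.04), gatB of galactitol uptake (2.60) and alaE (2.43); lower ones were ytfE, of iron-sulfur cluster repair (-2.87), flu, for the surface protein antigen 43 (301 ± 44.5 against 45.2 ± 2.15 FPKM, -2.70 ± 0.10), and modF (-2.49). Short genes listed at 0 in 1 of the groups were proM (0 and 0 in Δfur/Fe against 4097 and 4169 FPKM), yoaK (0 and 0 against 1025 and 2812), icdC (0 and 0 against 79.6 and 68.3), and, in the other direction, sdsR (301 and 255 FPKM against 0 and 0), ypaA (23.5 and 10.2 against 0 and 0) and torI (7.21 and 25.4 against 0 and 0).

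In all, limma called 290 genes between Δfur/DPD and Δfur/Fe, 194 higher and 96 lower, or 146 and 135 under quantile normalization, and fitted on these 4 libraries alone it called 3. The spread behind the 290 calls was shared with the WT libraries. Across all genes tested, replicates correlated at 0.974 in WT/Fe and 0.978 in WT/DPD, but at 0.929 in Δfur/Fe and 0.914 in Δfur/DPD. The calls of this comparison assume that all groups vary alike. Leaving out WT/Fe 1 or 2, WT/DPD 1 or 2, Δfur/Fe 2 or Δfur/DPD 2 left 143, 143, 125, 125, 143 and 159 calls, and the Δfur/Fe label is one of those that fur contradicted.

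**Figure D3:**
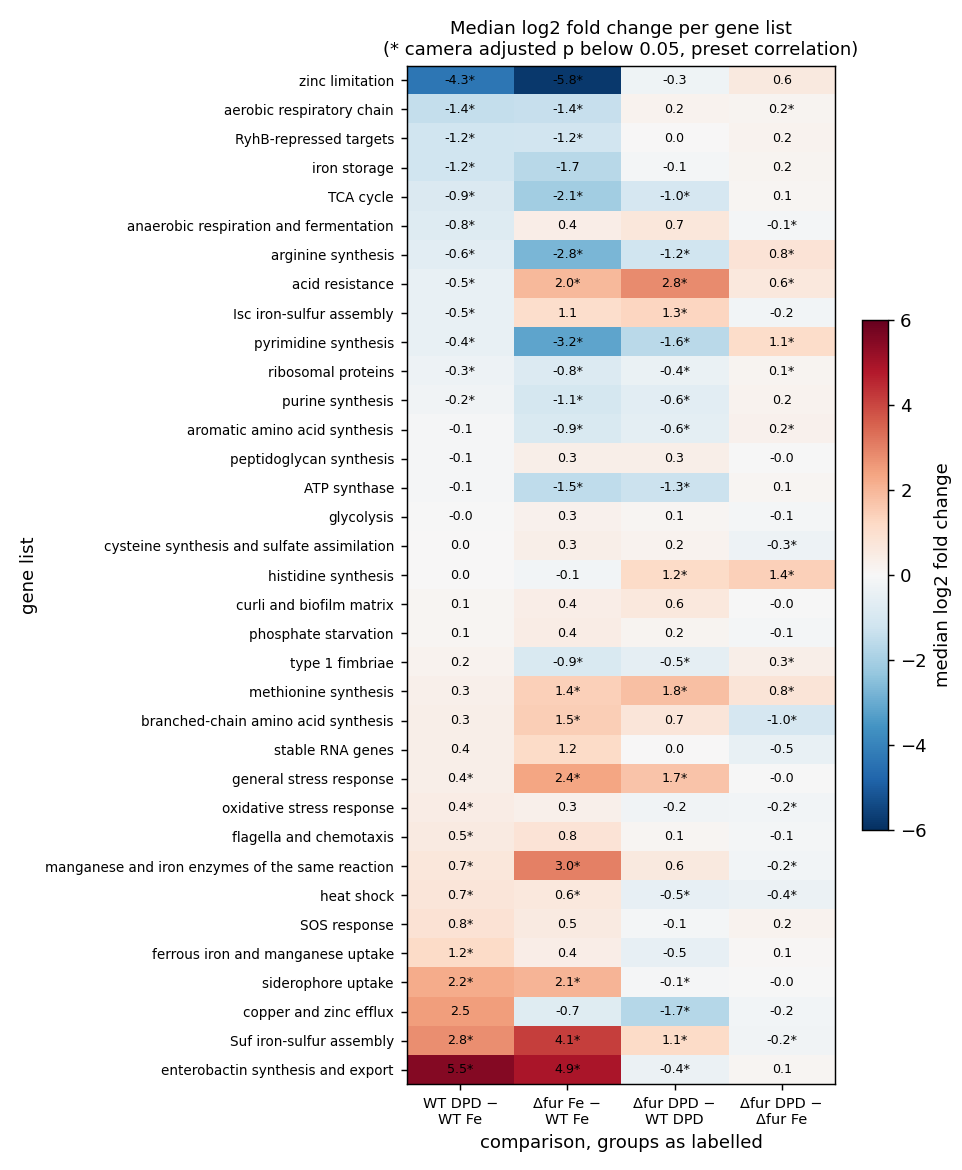
Median log2 fold change of each gene list down the plot in the 4 comparisons between labelled groups across it, with the value in each cell, red for higher and blue for lower. The enterobactin row reads 5.49 and 4.89 in the comparisons with WT/Fe and -0.36 and 0.11 in the other 2; a star marks camera adjusted p under 0.05 with the preset correlation.

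The chelation response (DPD minus Fe) differed between the labelled genotypes for the iron genes. All 9 enterobactin genes and all 26 siderophore uptake genes responded lower in the libraries labelled Δfur than in those labelled WT (9 and 26 adjusted over the list alone), with camera adjusted p = 2.9e-10 and 8.7e-19, and adjusted p = 0.097 and 0.095 with an estimated correlation. For entC the difference of the responses was -6.04 ± 0.17, for cirA -6.39 ± 0.32, for ryhB -6.46 ± 0.72, for nrdI -5.67 ± 0.19 and for fes -5.63 ± 0.20. The 6 Suf genes responded lower as well (6 adjusted over the list alone), sufS at -3.03. Camera for the Suf list gave adjusted p = 3.0e-07, and adjusted p = 0.046 with an estimated correlation. RyhB-repressed targets responded higher in 12 of 17 cases and lower in 1 (13 and 1 adjusted over the list alone), with sodB at 6.12 ± 0.23, fumA at 2.59 and sdhD at 2.74. Camera for the RyhB target list gave adjusted p = 6.1e-09, and adjusted p = 0.040 with an estimated correlation.

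Heat shock genes responded lower in 12 of 15 cases (13 adjusted over the list alone) and SOS genes in 14 of 16 (15 adjusted over the list alone). Camera for the heat shock and SOS lists gave adjusted p = 1.5e-08 and 1.5e-08, and adjusted p = 0.040 and 0.040 with an estimated correlation. In the aerobic respiratory chain 13 of 21 responded higher and 1 lower (15 and 1 adjusted over the list alone), nuoG by 1.85 and nuoC by 1.82. Camera for the respiratory chain list gave adjusted p = 9.1e-11, and adjusted p = 0.095 with an estimated correlation. The zinc genes ykgM, zinT and znuA responded higher by 10.91, 8.94 and 5.85, in a list with 6 of 7 higher (6 adjusted over the list alone, beside 1 lower so). Camera for the zinc limitation list gave adjusted p = 5.5e-05, and adjusted p = 0.12 with an estimated correlation. In all, limma called 840 of 3484 genes for the difference of responses, 387 higher and 453 lower, or 456 higher and 382 lower under median-ratio scaling. Leaving out WT/Fe 1, WT/Fe 2, WT/DPD 1 or WT/DPD 2 left 459, 467, 445 and 366 calls. Each response lies within 1 library set, and an exchange of the WT/DPD and Δfur/Fe labels would leave these values as they are.

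The differences Δfur/Fe minus WT/Fe and WT/DPD minus WT/Fe share their WT/Fe libraries. Genes such as entC, fes, sufB and nrdE rose and sodB, zinT and ykgM fell in both. Across 3484 genes, which are not independent replicates, the log2 differences correlated at r = 0.495 (0.600 over the protein-coding genes of at least 400 bp), beside a mean of 0.486 and a highest value of 0.667 over all these genes in 100 simulations of unchanged groups against shared controls. Their covariance was 0.759 against a simulated 0.125, a difference of 0.634. The differences had the same sign in 73.5% of genes, beside a mean of 66.8% in the simulations. Called in both and higher in both were 433 genes, against 217.7 for independent lists, and lower in both 237 against 84.0, while 57 were called in opposite directions. The simulations kept the shared WT/Fe libraries, and their highest covariance was 0.210. Noise in these libraries, at the simulated spread, is therefore argued against as the whole source of the covariance. The excess of 0.634 is what remains once that noise is taken off, and the simulations held no changed genes. The correlation r did not exceed its highest simulated value. The values for independent lists leave out the shared controls, so part of the excess in the counts may come from them. Anything particular to the WT/Fe cultures enters both comparisons, so neither excess is by itself a shared effect. Splitting the 2 WT/Fe libraries would leave 1 per comparison and was not done.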

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

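All tests of explanations in this part were chosen after the results they measure had been seen, while the test of the difference between the chelation responses was planned.

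The response to DPD differed between the libraries labelled Δfur and those labelled WT in 840 genes by limma's test of the difference itself. The largest positive differences of log2 fold change were 10.91 in ykgM, 8.94 in zinT, 6.12 in sodB and 5.85 in znuA, and the largest negative ones -6.46 in ryhB, -6.39 in cirA and -6.04 in entC. Further genes among the extremes were listed at 0 in at least 1 library, so only their highest value in any library is given: proM 4169 FPKM, yoaK 2812, ykgO 2506, proK 693, tisB 1118, yjjZ 3966 and sdsR 300.9, and a pair of transcripts without a symbol 215 and 896.

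Camera called 26 of 35 lists for the same difference, with the medians of log2 fold change below. With an estimated correlation 4 of the 26 stayed called (Suf assembly, RyhB-repressed targets, heat shock and SOS), and the other 22 had adjusted p of 0.095 to 0.50. Iron lists gave -5.47 for enterobactin synthesis, -2.25 for siderophore uptake, -1.11 for ferrous iron and manganese uptake, -2.99 for Suf assembly, 1.35 for iron storage, 1.11 for RyhB-repressed targets and -0.85 for manganese and iron enzymes of the same reaction. Energy lists gave 1.01 for the TCA cycle, 1.57 for the aerobic respiratory chain and 0.79 for anaerobic respiration. Stress lists gave 0.95 for acid resistance, -0.45 for the general stress response, -0.63 for oxidative stress, -1.004 for heat shock and -0.81 for SOS. Zinc limitation gave 5.85, phosphate starvation -0.26, flagella -0.59 and ribosomal proteins 0.48. Synthesis lists gave 1.42 for histidine, 1.54 for arginine, 0.72 for methionine, -1.10 for branched-chain amino acids, 0.33 for aromatic amino acids, 0.31 for purines and 1.54 for pyrimidines. The line of the table without an identifier held 7390.4 FPKM in Δfur/Fe 1 and 0 in the other 7 libraries, a signal in data that no comparison used.

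The fur transcript stood against the labels of the WT/DPD and Δfur/Fe groups. Exchanged labels of these groups need every library of both to be out of place, and 4 of 4 were, but this is the observation that raised the explanation and cannot bear it out. A wrong label on Δfur/Fe alone, as the whole cause, is argued against by the highest fur value in WT/DPD, which was 0. Failed estimates, which give 0, are argued against as the cause of the fur level in Δfur/Fe, where the lowest value was 805 FPKM. For the 0 in both WT/DPD libraries a failed estimate stays open, since a failure of fur alone and a true absence would be listed alike, and a wrong label on Δfur/Fe beside such a failure stays open with it. Silencing of fur by chelation in WT cells, with a mutant that still transcribes part of the locus (mean 823 FPKM in Δfur/Fe), cannot be told apart from an exchange, and both stay open as hypotheses. The overlapping leader gene uof was listed at 512 and 955 FPKM in WT/DPD and at 0 in all libraries labelled Δfur, which goes against silencing of the whole locus in WT/DPD, but as an 87 bp gene at 0 along that set like other short genes, and with strand not given, it was not taken to decide.

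The first principal component parted the 4 libraries labelled WT from the 4 labelled Δfur. Short genes as the whole source are argued against by its 75.9% of the variance among protein-coding genes of at least 400 bp, and scaling between libraries by the 2425 genes called for Δfur/Fe minus WT/Fe under median-ratio scaling. A library batch stays open: the fragment lengths of the sets lay 24 bp apart at the nearest, and as every library of a set shares its labelled genotype, batch and label cannot be told apart. The labelled genotype itself also stays open, untested. Under exchanged labels the same component would part cultures with Fe from cultures with DPD, which may make it a response to chelation.

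The zinc uptake genes were high in WT/Fe alone. Short genes as the source are argued against by the length of the shortest of zinT, znuA, znuB and znuC, 651 bp, and the library set by the fall of 4 of these 4 genes between WT/Fe and WT/DPD, whose libraries are of 1 set. Less zinc in the WT with Fe cultures may account for it: zntA, which exports zinc and was picked after its values were seen, was above WT/Fe in every library of the other 3 groups. By label the Δfur/Fe cultures had the same FeCl2, glucose and temperature, yet 6 of 7 zinc limitation genes were lower there. Less zinc in a medium common to all Fe cultures is thus argued against, though fur contradicted the Δfur/Fe label. The zinc content of the media was not given in the sources used here. Effects of iron supply or of fur on these genes were not tested apart from zinc, so less zinc in WT/Fe stays a hypothesis.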

How the results depend on the processing

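Of the alternatives reported here, the limits to protein-coding genes of at least 400 bp and to genes above 0 in all libraries were chosen after seeing the data, and the rest were planned. Fold changes of named genes were compared over only part of the alternatives. Other variance models, the 4 libraries of a contrast alone and the limits chosen after seeing the data were left out. Of the 11689 values compared, 10966 kept their side of the threshold, 570 lost their call, 153 gained one and 0 were reversed. A reversal was counted only where the original or the alternative value was called. A turn of sign between uncalled values thus counts as kept. List tests were compared only for an estimated correlation, the replicate block, pseudocounts of 0.1 and 10 and median-ratio scaling. Of these 875 list tests 773 kept their side of the threshold, 95 lost their call, 7 gained one and 0 were reversed, by the same rule. Of 125 counts and correlations 104 stayed within 1.5 times the original or its spread, 20 counts fell below that and 1 correlation moved. With a pseudocount of 0.1 the siderophore uptake list lost its camera call for Δfur/DPD minus WT/DPD. Fitted on its 4 libraries alone, Δfur/DPD minus Δfur/Fe gave 3 calls in place of 290, while the same setting gave 1109 in place of 800 for WT/DPD minus WT/Fe, 2460 in place of 2492 for Δfur/Fe minus WT/Fe and 1847 in place of 2040 for Δfur/DPD minus WT/DPD; the cause was not tested. A minimum absolute log2 fold change of 1, which by construction removes calls, left 237 for WT/DPD minus WT/Fe, 1180 for Δfur/Fe minus WT/Fe, 778 for Δfur/DPD minus WT/DPD, 98 for Δfur/DPD minus Δfur/Fe and 341 for the difference of responses. The correlation of Δfur/Fe minus WT/Fe with WT/DPD minus WT/Fe was 0.60 over coding genes of at least 400 bp; the cause was not tested. Leaving out each library in turn, with the lone library of a group assumed to vary like the others, gave 345 to 908 calls for WT/DPD minus WT/Fe, 125 to 343 for Δfur/DPD minus Δfur/Fe and 366 to 945 for the difference of responses. Counts fell by over 1.5 times without WT/Fe 1, WT/Fe 2, WT/DPD 1 or WT/DPD 2, to 420, 444, 399 and 345 in the first of these, 143, 143, 125 and 125 in the second and 459, 467, 445 and 366 in the last. For Δfur/DPD minus Δfur/Fe they did so also without Δfur/Fe 2 (143) or Δfur/DPD 2 (159). Pseudocounts, filters, variance models and scalings left the total of calls in each comparison within 1.5 times the original. Counts within a list could move further, as for ribosomal protein genes that fell in WT/DPD minus WT/Fe, 16 as deposited, 1 under quantile normalization and 25 under median-ratio scaling. Depth limits low genes, since 5 FPKM in a gene of 1000 bp rested on 34.4 to 44.5 fragments. DESeq2 and edgeR were not run, because the table used held no counts.

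With the replicate number as a replicate block the calls were 667, 2468, 1983, 208 and 688 in the same order of contrasts as for the minimum fold change. Deviations of same-numbered libraries from their group means correlated at -0.10 to 0.18 between pairs of groups, so the numbers were not taken as pairing.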

Other observations

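The gene lists described in this part were fixed in advance, and no test here was chosen after its result was seen. Between WT/DPD and WT/Fe, by label, the 8 tested genes of ferrous iron and manganese uptake gave 6 that rose (7 adjusted over the list alone), with mntH at 1.23 and feoA at 1.06. Camera for the ferrous iron list gave adjusted p = 8.2e-04, and adjusted p = 0.097 with an estimated correlation. Of 14 oxidative stress genes 7 rose and 1 fell (7 and 1 adjusted over the list alone). Camera for the oxidative stress list gave adjusted p = 0.0054, and adjusted p = 0.10 with an estimated correlation. Of 19 genes of anaerobic respiration and fermentation 11 fell and 1 rose (12 and 2 adjusted over the list alone). Camera for the anaerobic respiration list gave adjusted p = 2.7e-05, and adjusted p = 0.14 with an estimated correlation. Of 18 flagella and chemotaxis genes 3 rose (7 adjusted over the list alone). Camera for the flagella list gave adjusted p = 0.0041, and adjusted p = 0.097 with an estimated correlation. Ribosomal protein genes fell in 16 of 54 cases and rose in 1 (22 and 1 adjusted over the list alone; 1 fell under quantile normalization and 25 under median-ratio scaling), the riser being rpmE, for the zinc-binding form of protein L31, at 1.77. Camera for the ribosomal protein list gave adjusted p = 1.0e-10, and adjusted p = 0.11 with an estimated correlation.

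Between Δfur/Fe and WT/Fe, by label, 13 of 14 purine synthesis genes fell and 1 rose (13 and 1 adjusted over the list alone), and 13 of 16 aromatic amino acid synthesis genes fell (13 adjusted over the list alone), with aroF at -3.43. Camera for the purine and aromatic lists gave adjusted p = 6.6e-05 and 1.4e-05, and adjusted p = 0.34 and 0.28 with an estimated correlation. Branched-chain amino acid synthesis genes rose in 11 of 13 cases and fell in 2 (11 and 2 adjusted over the list alone), leuA by 3.37. Camera for the branched-chain list gave adjusted p = 0.019, and adjusted p = 0.30 with an estimated correlation. Type 1 fimbriae genes fell in 5 of 9 cases and rose in 1 (5 and 1 adjusted over the list alone), fimB at -3.23. Camera for the fimbriae list gave adjusted p = 0.022, and adjusted p = 0.28 with an estimated correlation. The stable RNA list, with several members listed at 0, had a median of 1.16 and a mean of -1.53, and its camera test pointed down (adjusted p = 0.75).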
